A study of Mus musculus with 20 samples.

How the data were processed

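Small RNA was sequenced from primary midbrain neuron cultures of C57Bl6/J mouse embryos of day 12.5. Per the labels, the ventral mesencephalon was dissected, the meninges were removed, and the dissociated cells were grown without serum in Neurobasal-A medium with B27 supplement. Cultures were collected on day 1 or day 5 in vitro (DIV1 and DIV5), with or without 10 ng/ml of GDNF (glial cell line-derived neurotrophic factor), which gave 4 groups of 5 replicate libraries and 20 libraries in all. RNA was extracted with Tri-reagent and the libraries were made with the TruSeq small RNA protocol. The labels do not say whether replicates came from separate animals or separate cultures, so every p-value measures only the spread between these libraries.

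The deposited values are raw read counts per mature miRNA, 1 file per library, with no normalization. Per the labels, the authors used cutadapt 1.8.1, STAR 2.4.1d and HTSeq, whose version is not given, with genome build mm10. The annotation of mature miRNAs is not stated. Each file lists 1886 mature miRNAs and 5 tally lines. The tally of reads without a feature was the only tally above 0. In 12 cases mature miRNAs with joined names share 1 line, such as miR-199b-3p with miR-199a-3p, and these were kept as 1 feature. A value for a mature arm cannot be assigned to 1 of several gene copies. Hairpin positions are from GENCODE vM21 on GRCm38, the assembly also called mm10.

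Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count miRNAs were removed with filterByExpr, which kept 542 of the 1581 miRNAs with at least 1 read, and the kept miRNAs held at least 99.9% of the counts of every library. Libraries were scaled with TMM factors, and levels are given as TMM-scaled CPM with the SD over 5 libraries. All 20 libraries entered 1 quasi-likelihood fit (glmQLFit with robust estimation, glmQLFTest) with 1 coefficient per group. The 5 contrasts were GDNF against control at DIV1, the same at DIV5, DIV5 against DIV1 without GDNF, the same with GDNF, and the difference of the GDNF effects at the 2 days (the interaction). A miRNA was called at a Benjamini-Hochberg adjusted p below 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Tests are two-sided.

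In total 17 lists of miRNAs were fixed before the data were examined, as were the tests and the rule for naming miRNAs. A list holds every tested arm of its miRNAs, and some lists share members. Lists with at least 3 tested arms, 15 of the 17, were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of each comparison. Beside each camera call made with all libraries and all arms stands the value with an estimated correlation. Camera compares a list with the other miRNAs, whereas fry, an alternative, asks whether the members move on balance in 1 direction. The naming rule took, among calls with a mean of at least 10 CPM, the 10 largest increases and the 10 largest decreases for each GDNF comparison and for DIV5 against DIV1 without GDNF. Where fewer than 10 miRNAs were called, it took the 10 with the smallest p. It added the 5 interaction values with the smallest p, the arms of the miR-183 cluster, the 2 most abundant members of each list and the 5 most abundant miRNAs. Other members of a list are named as examples chosen after their values were seen, and so are miR-10a, miR-10b, miR-199 and miR-214. The single-miRNA comparisons of 3 cluster members used an exact permutation test of log2 CPM with a pseudocount of 0.5, in a family of 12 tests. Library measures were also compared with exact permutation tests, for which 5 libraries against 5 cannot give a p below 0.00794.

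The total count per library was between 420118 and 4324505. At DIV1 it was between 686793 and 1557885 without GDNF and between 420118 and 1761023 with GDNF, and at DIV5 between 1061619 and 4324505 without and between 1781030 and 3983722 with GDNF. A single read was therefore worth 0.231 to 2.38 CPM, and a count of 0 allows a level of up to 0.694 to 7.14 CPM (3 reads). Reads without molecular identifiers are not independent molecules, so these limits cover counting error only. The same fit was tested on simulated data in which 200 miRNAs were given known changes. It recovered 30.3%, 65.2% and 93.7% of the changes of 1.5-, 2- and 4-fold for GDNF at DIV1, and 43.3%, 79.7% and 98.5% for GDNF at DIV5. Of the calls made there, 2.4% and 2.04% were false. The simulated counts were drawn independently for each library, without batches, pairs or libraries that stand apart. With 200 changed miRNAs the adjusted threshold is also easier to pass than with few changes. These shares may therefore not hold for the GDNF comparisons. No pair of libraries in a group was near-identical: the lowest chi-square per degree of freedom was 10.6.

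The libraries were checked for structure outside the groups. Within DIV5, libraries with the same replicate number deviated from their group means together (correlations across miRNAs of 0.21 to 0.53), which met the rule for pairing (each above 0.1). At DIV1 the correlations were 0.022 to 0.51, which did not meet it. The same number was the best partner for only 2 of 5 libraries at DIV5, against 3 of 5 at DIV1. The other best partners at DIV5 were 1 with 2, 3 with 5 and 5 with 4, each on the same side of the division described next, so the correlations do not separate pairs from that division. Across days the correlations of the same number were -0.11 to 0.15, which did not meet the rule either. Single arms could still follow a number across days, as miR-199a-5p did in replicate 1 (described below). A shared source of some libraries is therefore not excluded. At DIV5 the libraries of replicates 1 and 2 differed from those of replicates 3 to 5 in depth and in the share of reads without a feature, and they are called 2 batches here. The main fit has no term for batch or replicate number, so this division is part of its spread within groups. Whether sequencing, dissection or tissue sets them apart was not tested. DIV5 control libraries 1 and 5 stood apart from the other 3 DIV5 controls in 40 arms, each at least 2-fold higher in both. Not every 1 of these arms exceeded all other libraries: miR-184-3p had 13.5 CPM in library 5 and up to 20.8 CPM at DIV1. The labels name no batches.

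Alternatives to the choices above were DESeq2 size factors (RLE) or upper-quartile scaling, no filter, a filter at a mean of 10 CPM, the DESeq2 1.42.0 Wald test, limma voom, a fit of only the groups compared, a replicate term over all libraries, camera with an estimated correlation, fry, 1 arm per miRNA, the 10 in place of the 5 most abundant miRNAs, and each library left out in turn. Added after the data were seen were a replicate term within each day, a fit without the 2 DIV5 control libraries that stand apart, and both of these together. Fits of each DIV5 batch with all DIV1 libraries, and the exact test of miR-182-5p and miR-183-5p, were also added then. The DIV1 libraries thus share in the estimate of the spread in each batch fit. The replicate term within each day cannot estimate a change between days. No library was left out of the values below unless this is said.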

Results

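The series asks how GDNF changes the miRNAs of cultured embryonic midbrain neurons on the first and the fifth day in vitro, and its title names miR-182 and miR-183. miR-181a-5p, abundant in neural tissue, was the most abundant miRNA, with 15.8% ± 1.35 of all counts (SD, n = 20). miR-9-5p, a miRNA of neural progenitors and young neurons, followed with 7.18% ± 1.03, then miR-6239 with 5.83% ± 3.68, miR-99b-5p with 4.54% ± 1.17 and miR-92b-3p with 3.65% ± 1.79. The share of miR-6239 was the most variable of these and ranged from 0.894% to 13.4% between libraries. These 5 miRNAs together held 41.3% ± 1.85 of the counts at DIV1 without GDNF and 32.1% ± 2.28 at DIV5 without GDNF (n = 5 each, exact permutation p = 0.00794, adjusted over 4 comparisons p = 0.0318). With GDNF the shares were 40.1% ± 1.64 and 34.7% ± 2.26 (exact permutation p = 0.0159, adjusted p = 0.0318). GDNF against control gave differences of -1.21 percentage points at DIV1 (exact p = 0.302) and 2.55 at DIV5 (exact p = 0.111). Without DIV5 control library 2 the DIV5 difference was 3.47 (unadjusted exact p = 0.0397; between 0.0397 and 0.23 over the 10 libraries left out). Total counts were higher at DIV5 than at DIV1, 2843000 against 1006000 without GDNF (exact p = 0.0238, adjusted p = 0.0476) and 2981000 against 1034000 with it (exact p = 0.00794, adjusted p = 0.0318). The difference without GDNF did not hold on every library: without DIV1 control library 3, 4 or 5 the unadjusted exact p was 0.0556, 0.0556 and 0.0635 (between 0.00794 and 0.0635 over the 10 libraries left out). The number of miRNAs detected, 878.2 and 862 at DIV1 and 1047 and 1058 at DIV5 without and with GDNF, follows depth and is not read as biology.

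At DIV5, miR-182-5p was higher in cultures grown with GDNF. Its level was 1182 ± 317 CPM with GDNF and 431.6 ± 255 CPM without (SD, n = 5 each), a 2.75-fold difference, and it was higher with GDNF in 5 of 5 pairs of libraries with the same replicate number. miR-183-5p had 183.7 ± 37.9 CPM with GDNF and 90.17 ± 56.6 CPM without, and miR-96-5p had 4.26 ± 0.553 and 1.77 ± 1.25 CPM, each also higher in 5 of 5 pairs. The ranges of miR-182-5p barely overlapped (up to 832.3 CPM without and from 824.9 CPM with GDNF). Those of miR-96-5p did not overlap (up to 2.962 and from 3.743 CPM). For these arms other pairings would give the same or nearly the same count, so the pair counts add little to the group differences. miR-182, miR-183 and miR-96 form the miR-183 cluster, which is transcribed together and best known from sensory organs. On build mm10, Mir182 lies on chromosome 6 at 30165918 to 30165992, Mir96 at 30169446 to 30169551 and Mir183 at 30169668 to 30169737, all on the minus strand, within 3820 bp and outside other annotated genes.

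In the edgeR fit, miR-182-5p had a log2 fold change of 1.46 (SE 0.277, adjusted p = 0.0193) and was the only 1 of 542 miRNAs called for GDNF at DIV5, where 88 had an unadjusted p under 0.05. miR-183-5p (log2 1.05, SE 0.307, adjusted p = 0.0845) and miR-96-5p (log2 1.44, SE 0.41, adjusted p = 0.075) were not called over all miRNAs. miR-183-3p had a log2 value of -0.0035 (adjusted p = 0.997). An SE taken from the F statistic is not stable at so small a value and is not given. Without DIV5 control libraries 1 and 5 the log2 value of this rare arm (mean 2.14 CPM without and 1.89 CPM with GDNF in all libraries) was 1.07 (adjusted p = 0.999). Adjusted over the list alone, 3 of the 4 tested arms of the cluster passed, with an edgeR adjusted p of 0.000142 for miR-182-5p and 0.0037 for miR-183-5p and for miR-96-5p. The series title names miR-182 and miR-183, members of this list, so its count is not independent evidence. The list was higher with GDNF in camera (median log2 1.24, adjusted p = 1.34e-06), but not with an estimated correlation (adjusted p = 0.0673), and fry gave an adjusted p of 0.0206 (over 23 alternatives between 1.48e-19 and 0.0673, called in 21). The other alternative without a call was that of DIV5 replicates 1 and 2 (median 0.50, camera adjusted p = 0.061). DESeq2 called 26 miRNAs (7 higher, 19 lower), miR-183-5p and miR-96-5p among the higher ones (adjusted p = 0.0257 and 0.0227), and limma voom called 1.

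**Figure D1:**
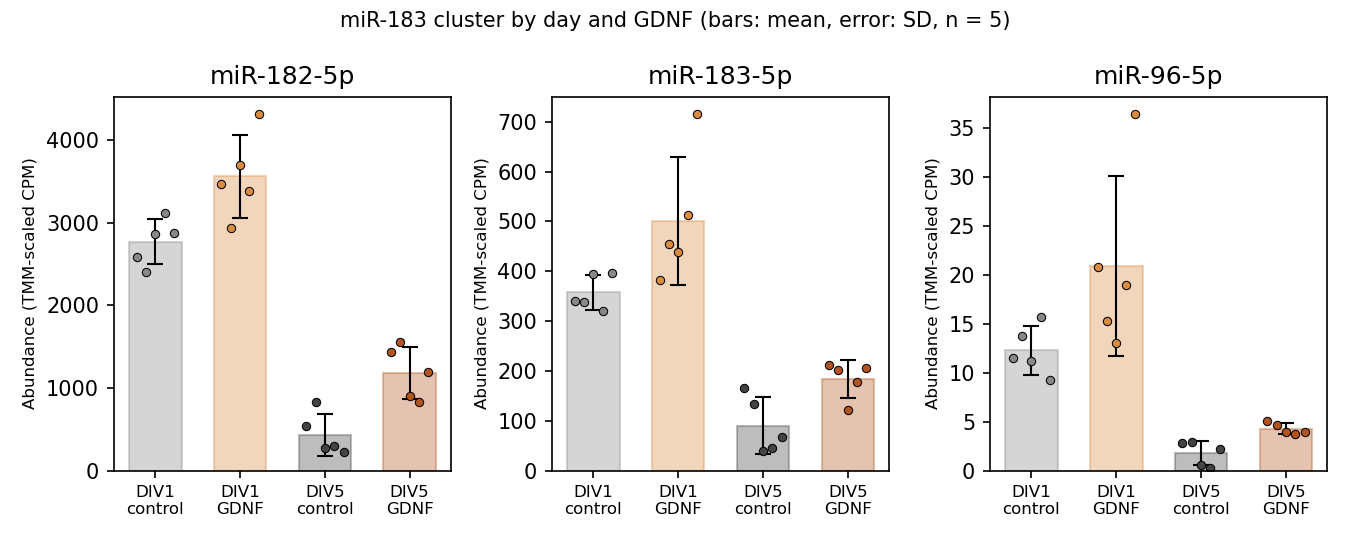
Levels of miR-182-5p, miR-183-5p and miR-96-5p in TMM-scaled CPM (vertical axis, starting at 0) in the 4 groups. Bars are means and error bars SDs of 5 libraries, and points are single libraries; at DIV5 the mean of miR-182-5p is 431.6 CPM without and 1182 CPM with GDNF, against 2771 and 3558 CPM at DIV1.

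The call of miR-182-5p at DIV5 depended on the fit and on the libraries used. With a replicate term within each day, 3 miRNAs were called, all higher with GDNF: miR-182-5p, miR-183-5p (log2 1.24, adjusted p = 0.0197) and miR-148a-3p. Within DIV5 replicates 1 and 2, miR-182-5p had a log2 value of 1.06 (adjusted p = 0.0128) and miR-183-5p of 0.37 (adjusted p = 0.469). Within replicates 3 to 5 the values were 1.91 (adjusted p = 8.41e-07) and 1.76 (adjusted p = 9.07e-05). Both batch fits kept all DIV1 libraries, which share in the estimate of the spread. Their p-values therefore do not rest on the DIV5 libraries alone. Without DIV5 control libraries 1 and 5 no miRNA was called by edgeR and 8 had an unadjusted p under 0.05. miR-182-5p, miR-183-5p and miR-96-5p then had log2 values of 1.36, 1.41 and 2.3, each with an adjusted p of 0.053. The value of miR-96-5p rests on few reads. It had 2.96, 0.593 and 0.303 CPM in DIV5 control libraries 2, 3 and 4, where 1 read is worth 0.942, 0.231 and 0.337 CPM. Over 24 alternatives the log2 value of miR-182-5p lay between 1.06 and 1.91 and its adjusted p between 8.41e-07 and 0.442, and it was called in 20. Leaving out DIV5 GDNF library 1 or 2 also ended the call (adjusted p = 0.0829 and 0.0918), and in a fit of the 10 DIV5 libraries alone the adjusted p was 0.442. miR-183-5p was called in 7 of 24 alternatives (log2 between 0.37 and 1.76, adjusted p between 9.07e-05 and 0.469), 2 of which left out DIV5 control library 1 (log2 1.43, adjusted p = 0.0158) or 2 (log2 1.23, adjusted p = 0.0233).

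Of the other 9 miRNAs with the smallest p for GDNF at DIV5, none was called in the edgeR fit (adjusted p between 0.055 and 0.0592). All 9 were called by DESeq2 (adjusted p between 0.00167 and 0.0203) and by edgeR with the filter at 10 CPM (adjusted p = 0.0467 for each). miR-375-3p, a miRNA of neuroendocrine cells, had 405.4 ± 133 CPM with GDNF and 242.6 ± 57 without (log2 0.74). It was called higher in 9 of 23 alternatives (adjusted p between 3.61e-05 and 0.442 over all). Within DIV5 replicates 1 and 2 it was called (log2 1.13, adjusted p = 0.0227), and within replicates 3 to 5 it was not (log2 0.42, adjusted p = 0.424). miR-148a-3p had 3418 ± 319 and 2443 ± 436 CPM (log2 0.48), called in 7 of 23. The other 7 had negative values: miR-24-3p -3.11, miR-7a-5p -2.91, miR-411-3p -2.21, miR-185-5p -2.20, miR-379-5p -2.12, miR-425-3p -1.98 and miR-455-3p -1.70. All 7 belong to 40 arms that were at least 2-fold higher in DIV5 control libraries 1 and 5 than in the mean of the other 3 DIV5 controls. miR-7a-5p, for example, had 2290 and 4540 CPM in those libraries and at most 304 CPM in any other DIV5 library. In the same libraries miR-7a-1-3p, from the opposite arm of a miR-7a hairpin, had 53.7 and 55.9 CPM, against 48.1 to 79.1 CPM in the other DIV5 libraries. All 19 lower calls of DESeq2 were among these 40 arms. Without DIV5 control library 2, 3 or 4 the edgeR count was 43, 32 or 37, and 25, 24 and 26 of the lower calls were such arms.

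**Figure D2:**
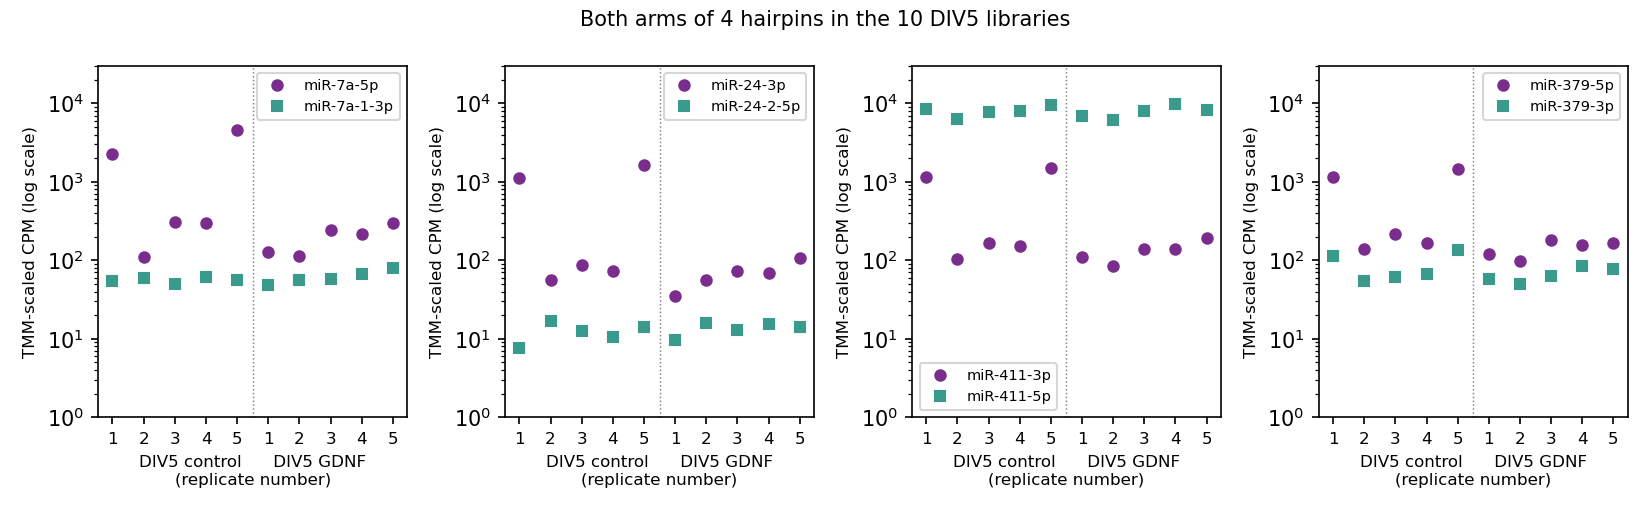
Levels of both arms of 4 hairpins in TMM-scaled CPM (vertical axis, log scale) in the 5 control and 5 GDNF libraries of DIV5, by replicate number (horizontal axis). In control libraries 1 and 5 miR-7a-5p had 2290 and 4540 CPM, against at most 304 CPM in the other 8, while miR-7a-1-3p stayed between 48.1 and 79.1 CPM in all 10. miR-379-3p was higher in control libraries 1 and 5 too, with 112.6 and 134.9 CPM against 49.64 to 83.84 CPM in the other 8.

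No list other than the miR-183 cluster was called for GDNF at DIV5 (adjusted p between 0.568 and 0.862 for 14 lists), except Dlk1-Dio3 without DIV5 control library 2 (median -0.10, adjusted p = 0.0322). In edgeR none of the 17 neuron-enriched arms was called (median log2 -0.06), with miR-124-3p at -0.0046 and miR-128-3p at -0.25. In edgeR the dopaminergic neuron list had 0 of 7 arms called (median -0.0052), the activity-regulated list 0 of 7 (median -0.10), the Dlk1-Dio3 list 0 of 81 (median -0.06) and the miR-17-92 list 0 of 25 (median -0.02). Adjusted over the list alone, 2 arms passed in the dopaminergic list, 1 in the activity-regulated list, 3 in Dlk1-Dio3, 2 in the astrocyte and glial list and 2 in the vascular and mesenchymal list, all with lower values with GDNF. Of the arms raised in DIV5 control libraries 1 and 5, those lists hold 2, 1, 11, 2 and 3. The lists of miR-9 and neurogenic miRNAs (median 0.10), let-7 with miR-125 and miR-99/100 (0.01), miR-290 and miR-302 (0.15), oligodendrocyte lineage (-0.18), astrocytes and glia (-0.27), erythroid cells (0.13), vascular and mesenchymal cells (0.07), epithelial and ependymal cells (0.08) and stress and injury (0.03) had no arm called by edgeR. DESeq2 called members of 6 of these lists, all lower with GDNF and all raised in DIV5 control libraries 1 and 5: miR-137-3p (neuron-enriched), miR-7a-5p and miR-7b-5p (dopaminergic), miR-146b-5p (activity-regulated), miR-379-5p, miR-411-3p, miR-370-3p and miR-494-3p (Dlk1-Dio3), miR-92b-5p (miR-17-92), and miR-140-5p and miR-152-3p (vascular and mesenchymal). Camera's direction was down for the vascular and the stress lists, opposite to their medians, and the means of the let-7 list and of the list of miR-290 and miR-302 were negative.

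At DIV1 the same cluster had higher mean levels with GDNF, but none of its arms passed in the edgeR fit. miR-182-5p had 3558 ± 503 CPM with GDNF and 2771 ± 276 CPM without (n = 5 each, log2 0.36, SE 0.271, adjusted p = 1), and the ratio within pairs of the same number was between 1.08 and 1.5. miR-183-5p had 500.8 ± 129 and 358 ± 35.1 CPM (log2 0.48, SE 0.303), and miR-96-5p 20.9 ± 9.18 and 12.3 ± 2.48 CPM (log2 0.66, SE 0.354). Each was higher with GDNF in 5 of 5 pairs. The arm miR-183-3p had a log2 value of 0.27 (SE 0.533).

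edgeR called 0 of 542 miRNAs for GDNF at DIV1, with 7 at an unadjusted p under 0.05. DESeq2 and limma voom also called 0. The fit of all libraries uses 1 estimate of the spread per miRNA: in a fit of the 10 DIV1 libraries alone edgeR gave an unadjusted p of 0.005 for miR-182-5p and 0.00901 for miR-183-5p, in place of 0.198 and 0.129, with an adjusted p of 0.998 for each. Exact permutation tests of single miRNAs, added after the data were seen, gave p = 0.0159 for miR-182-5p (adjusted over 12 tests p = 0.0212), p = 0.0238 for miR-183-5p (adjusted p = 0.0286) and p = 0.0397 for miR-96-5p (adjusted p = 0.0397). At DIV5 the exact tests gave p = 0.0159, 0.0317 and 0.00794 (adjusted p = 0.0212, 0.0346 and 0.0136). Adjusted over the list alone, 0 of the 4 arms of the cluster passed in edgeR at DIV1. The list was called higher by camera (median log2 0.42, adjusted p = 0.0205), but with an estimated correlation the adjusted p was 0.908, and fry gave an adjusted p of 0.948 (over 21 alternatives between 1.8e-06 and 0.948, called in 15). Leaving out DIV1 control library 1 or 5 or DIV1 GDNF library 5 ended the camera call (adjusted p = 0.0674, 0.0562 and 0.228).

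Of the other miRNAs with the smallest p for GDNF at DIV1, all had an adjusted p of 1. let-7f-1-3p had a log2 value of 2.04, miR-669d-5p 1.38, miR-6516-5p 1.12, miR-19a-5p 0.78, miR-1981-5p 0.71 and miR-673-5p 0.26, and miR-149-3p had -1.89, miR-544-5p -1.59, miR-3473d -0.98 and miR-1957a -0.66. The largest of these changes were in rare arms. Mean levels without and with GDNF were 0.676 and 2.65 CPM for let-7f-1-3p and 5.33 and 1.1 CPM for miR-149-3p. They were 3.56 and 1.32 CPM for miR-544-5p and 2.41 and 6.04 CPM for miR-669d-5p. At DIV1 a count of 0 allows a level of up to 1.7 to 7.14 CPM. None of the other 14 lists was called, with adjusted p between 0.828 and 0.868. Without DIV1 control library 1 camera called Dlk1-Dio3 higher (median 0.13) and let-7 lower (median -0.08, adjusted p = 0.0162 for each). Their medians were small: neuron-enriched 0.07, miR-9 and neurogenic 0.02, activity-regulated 0.11, let-7 -0.0082, miR-17-92 0.02, miR-290 and miR-302 0.16, Dlk1-Dio3 0.04, dopaminergic -0.06, oligodendrocyte 0.16, astrocyte -0.03, erythroid 0.13, vascular -0.06, epithelial 0.02 and stress -0.06. For let-7, dopaminergic and neuron-enriched arms the mean had the opposite sign to the median, as it had for the epithelial list, where camera's direction was down. The 5 most abundant miRNAs had log2 values of 0.06 (miR-181a-5p), 0.03 (miR-9-5p), -0.46 (miR-6239), 0.07 (miR-99b-5p) and 0.04 (miR-92b-3p). At DIV5 these were 0.15, 0.15, 0.13, 0.49 and 0.13, none called. miR-6239 and miR-1957a were lower with GDNF in 5 of 5 pairs of the same number at DIV1. In 1 alternative, the fit with a replicate term within each day and without DIV5 control libraries 1 and 5, edgeR called both lower. miR-6239 then had a log2 value of -0.52 (adjusted p = 0.0311; over the alternatives between 0.0311 and 1) and miR-1957a of -0.72 (adjusted p = 0.000604; between 0.000604 and 1). Those DIV5 libraries are no part of the DIV1 comparison and enter it only through the common fit, and with the replicate term alone the adjusted p was 0.998 for miR-6239 and 0.142 for miR-1957a.

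The GDNF effects at the 2 days were compared directly. With all libraries no miRNA had a called difference between them in edgeR, DESeq2 or limma voom, and 50 of 542 had an unadjusted p under 0.05 in edgeR (smallest adjusted p 0.436). The difference was 1.10 on the log2 scale for miR-182-5p (SE 0.384, edgeR adjusted p = 0.436, over 32 alternatives between 0.00039 and 0.997), 0.57 for miR-183-5p (adjusted p = 0.794), 0.78 for miR-96-5p and -0.27 for miR-183-3p. Without DIV5 control libraries 1 and 5 the difference for miR-183-3p was 0.83 (adjusted p = 0.997). In 3 of the alternatives miR-182-5p was called: without DIV5 control library 2 (adjusted p = 0.0385), in DIV5 replicates 3 to 5 (log2 1.58, adjusted p = 0.00039), each as the only miRNA, and without DIV5 control libraries 1 and 5 with a replicate term within each day (1.03, adjusted p = 0.00137). In the last of these miR-375-3p, miR-1957a, miR-540-3p and miR-6937-5p were called too. The 5 smallest p-values belonged to miR-425-3p (-2.47), miR-379-5p (-2.59), miR-146b-5p (-1.37), miR-7a-5p (-3.26) and miR-24-3p (-3.30), all of which had their highest levels in DIV5 control libraries 1 and 5. The miR-183 cluster was the only list called by camera (median difference 0.67, adjusted p = 0.0158). That call was absent with an estimated correlation (adjusted p = 0.895), in fry (0.619), in DIV5 replicates 1 and 2 (0.944) and without DIV1 GDNF library 3 (0.073), DIV5 control library 3 (0.378) or 4 (0.512) or DIV5 GDNF library 5 (0.13), and over 32 alternatives the adjusted p lay between 7.62e-11 and 0.944. The other 14 lists had adjusted p between 0.764 and 0.916. Across the 542 miRNAs, which are not independent replicates, the GDNF fold changes at the 2 days had a Pearson r of -0.063 and a Spearman rho of -0.0909, and 45% had the same sign.

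Between DIV1 and DIV5 without GDNF, miRNAs of proliferating cells fell and neuronal miRNAs changed in both directions. Of the 25 arms of the miR-17-92 cluster and its paralogues, which are linked to MYC and E2F in dividing cells, 23 fell and none rose. miR-92a-3p fell from 54660 ± 9240 to 8213 ± 1750 CPM (n = 5 each, log2 -2.74, SE 0.172), miR-92b-3p by 1.64 on the log2 scale, miR-106a-5p from 40 ± 10.6 to 6.78 ± 3.7 CPM (log2 -2.53) and miR-20b-5p from 53 ± 15.8 to 9.14 ± 0.909 CPM (log2 -2.53). The list was lower in camera (median log2 -1.20, adjusted p = 7.52e-14), and this call held with an estimated correlation (adjusted p = 0.00106). The arms not called were miR-19a-5p and miR-92b-5p. All 4 arms of the miR-183 cluster also fell: miR-182-5p to 0.155-fold (log2 -2.69, SE 0.289), miR-183-5p by 2.01 on the log2 scale, miR-96-5p by 2.98 and miR-183-3p by 2.23 (camera adjusted p = 0.00181, with an estimated correlation adjusted p = 0.21). The arms miR-302a-3p (log2 -1.30) and miR-302b-3p (log2 -1.38), of a cluster known from pluripotent cells, fell, and miR-302d-3p was not called with all libraries, at -0.57 (camera adjusted p of the list of miR-290 and miR-302, 0.313).

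Of the 17 neuron-enriched arms 10 rose and 4 fell. miR-129-2-3p rose from 78 ± 18.8 to 1408 ± 696 CPM (n = 5 each, log2 4.19, SE 0.342), miR-124-3p, the classic neuronal miRNA, from 2359 ± 276 to 6064 ± 165 CPM (log2 1.36, SE 0.106), and miR-128-3p from 2899 ± 973 to 8841 ± 3290 CPM (log2 1.61). The arms that fell were miR-124-5p (log2 -1.23), miR-128-1-5p (-0.71), miR-138-1-3p (-0.63) and miR-153-5p (-0.45). Camera did not call the list (median log2 0.71, adjusted p = 0.0594, with an estimated correlation adjusted p = 0.345). With only the more abundant arm of each miRNA it did (7 of 8 rose, 1 fell, median 1.15, adjusted p = 0.000833). Leaving out 1 library also passed it for DIV1 control library 2, 3, 4 or 5 (adjusted p = 0.0246, 0.0332, 0.0347 and 0.029) and DIV5 control library 3, 4 or 5 (0.0426, 0.0454 and 0.0268). It passed in fry (adjusted p = 2.14e-05) as well. Camera called it without a filter (0.000376), with DIV5 replicates 1 and 2 only (0.00476) and in a fit of only the groups compared (0.0369).

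Activity-regulated miRNAs rose, 6 of 7 arms. miR-132-3p, a CREB target in neurons, rose from 194.1 ± 42.1 to 978.2 ± 600 CPM (log2 2.34, SE 0.305), miR-132-5p by 2.68 on the log2 scale, miR-212-5p by 1.56 and miR-146b-5p by 2.38. The list was higher in camera (median 1.56, adjusted p = 0.00267; with an estimated correlation adjusted p = 0.0818). Of the 81 arms from the imprinted, brain-enriched Dlk1-Dio3 cluster 51 rose, among them miR-376b-5p (log2 3.09), miR-434-3p (1.11, from 9246 ± 1860 to 19920 ± 2780 CPM) and miR-127-3p (0.40). miR-679-5p, miR-1197-3p, miR-758-3p and miR-409-3p fell. Camera called this list higher (median 0.89, adjusted p = 6.19e-07), but not with an estimated correlation (adjusted p = 0.345). In the dopaminergic neuron list 2 of 7 arms rose, miR-7b-5p (log2 4.85) and miR-7a-5p (log2 4.49), both known from neuroendocrine cells. Both are among the arms raised in DIV5 control libraries 1 and 5, without which the rise was 7.44-fold in place of 28.9-fold and 3.62-fold in place of 22.5-fold. In the same list miR-34c-5p had 0.0075 (camera adjusted p of the list 0.467).

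Markers of other cell types moved apart. The endothelial miR-126a-3p fell (log2 -1.49), as did the smooth muscle miRNAs miR-143-3p (from 3276 ± 474 to 766.6 ± 403 CPM, log2 -2.10), miR-145a-3p (-2.51) and miR-145a-5p (-1.46), whereas miR-140-3p, miR-140-5p and miR-152-3p rose (vascular and mesenchymal list, 3 up and 4 down of 13, camera adjusted p = 0.41). Without DIV5 control libraries 1 and 5, miR-140-3p was not called (adjusted p = 0.0654), and 1 arm of this list rose and 4 fell. The red cell miRNAs miR-451a (log2 -2.10) and miR-144-5p (-2.28) fell and miR-486a/b-5p rose by 0.80, and camera did not call the erythroid list (list adjusted p = 0.688). The leukocyte miRNA miR-142a-5p fell (-2.24) and miR-155-5p had -0.41; with 2 tested arms this list was not tested, nor was the muscle list, whose single tested arm, miR-208b-3p, had 1.04 (adjusted p = 0.084). Of the glial miRNAs, miR-219a-1-3p (-1.06) and miR-219a-2-3p (-1.02) fell and miR-338-5p rose (2.11) in the oligodendrocyte list (list adjusted p = 0.467). In the astrocyte list 6 of 11 arms rose and 2 fell, with miR-31-5p at 1.75 and miR-29c-3p at 1.24, while miR-21a-5p had -0.18 and miR-26a-5p 0.0053 (list adjusted p = 0.313). Without DIV5 control libraries 1 and 5, 4 of 10 astrocyte arms rose and 1 fell (median 0.28 in place of 0.99). In the epithelial and ependymal list miR-204-5p rose (1.34) and 3 arms fell (list adjusted p = 0.796). Let-7 with miR-125 and miR-99/100 had 11 up and 5 down of 31 (list adjusted p = 0.467), with miR-125b-5p among those that rose (0.66). The miR-9 and neurogenic list had 4 up and 6 down of 14 (list adjusted p = 0.313), and its most abundant members miR-181a-5p (-0.18) and miR-9-5p (-0.11) were not called. The stress and injury list had 5 up and 1 down of 16 (list adjusted p = 0.325), with miR-34a-5p at 1.20. For the oligodendrocyte list median and mean differed in sign. In fry the stress (adjusted p = 6.72e-06), astrocyte (0.000172) and dopaminergic (0.00105) lists passed upward. The oligodendrocyte (0.000657), miR-290 and miR-302 (0.00172) and miR-9 and neurogenic (0.00211) lists passed downward. The let-7, erythroid, vascular and epithelial lists did not pass. Camera without a filter passed let-7 (0.0112), stress (0.0219) and astrocyte (0.0432) upward and miR-290 and miR-302 (0.0355) downward.

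In all, 329 of 542 miRNAs were called between the days without GDNF, 170 higher and 159 lower at DIV5, of which 107 and 88 changed at least 2-fold. DESeq2 called 336 and limma voom 315. Further large decreases were those of miR-224-5p (log2 -2.50), miR-92a-1-5p (-2.32) and miR-712-5p (-2.15), and miR-6239 fell by 1.96. Of the 170 that rose, 28 are arms raised in DIV5 control libraries 1 and 5, which include 8 of the 10 largest increases. Without those libraries 285 were called (145 higher, 140 lower), 260 of them also called with all libraries. The rise was then 2.12-fold in place of 16.9-fold for miR-24-3p, 3.62-fold in place of 22.5-fold for miR-7a-5p, 7.44-fold in place of 28.9-fold for miR-7b-5p, 2.38-fold in place of 8.49-fold for miR-379-5p, 2.45-fold in place of 10.5-fold for miR-411-3p, 3.34-fold in place of 9.86-fold for miR-137-3p and 4.32-fold in place of 8.53-fold for miR-376b-5p. miR-3068-5p (log2 4.18) dropped below the filter. miR-129-2-3p (log2 4.29) and miR-1298-3p (log2 3.31 against 3.16) did not lose size. In Dlk1-Dio3 40 of 80 arms rose and 4 fell without these libraries (median 0.60, adjusted p = 1.44e-06), and in the activity-regulated list 6 of 7 rose (median 1.45, adjusted p = 0.00122), with miR-132-3p at 1.68 and miR-146b-5p at 1.56. These calls are at the preset correlation; with all libraries both were lost at the estimated one (adjusted p = 0.345 and 0.0818). Within the batches of DIV5, 246 were called with replicates 1 and 2 and 332 with replicates 3 to 5.

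With GDNF, the change from DIV1 to DIV5 had much the same members. Of 542 miRNAs 284 were called, 136 higher and 148 lower (DESeq2 297, limma voom 288). In total 245 were called in the same direction with and without GDNF, 117 higher and 128 lower, and none in opposite directions, where independent lists of these sizes would share 42.7 and 43.4. Across miRNAs the log2 changes had a Pearson r of 0.862 and a Spearman rho of 0.881. All 25 arms of the miR-17-92 list fell (median -1.40, adjusted p = 4.42e-17, with an estimated correlation adjusted p = 0.00095), miR-92a-3p by 2.41 and miR-106a-5p by 3.03 on the log2 scale. All 7 activity-regulated arms rose (median 1.09, adjusted p = 0.0107, with an estimated correlation adjusted p = 0.138), and in Dlk1-Dio3 44 of 81 rose and 3 fell (median 0.66, adjusted p = 9.35e-07, with an estimated correlation adjusted p = 0.294). All 4 arms of the miR-183 cluster fell (median -1.90, adjusted p = 0.0141, with an estimated correlation adjusted p = 0.294), miR-182-5p to 0.332-fold (log2 -1.59, SE 0.277) and miR-183-5p to 0.368-fold (log2 -1.44).

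Of the neuron-enriched arms 8 rose and 3 fell with GDNF (list adjusted p = 0.0672, 0.00186 with 1 arm per miRNA, and 0.0455, 0.0375, 0.0307 and 0.0468 without DIV1 GDNF library 2, 4 or 5 or DIV5 GDNF library 4), with miR-129-2-3p at 3.86, miR-128-3p at 1.33 and miR-124-3p at 1.31 on the log2 scale. Of the miRNAs with the largest increases without GDNF, miR-7b-5p (2.64), miR-137-3p (1.67), miR-1298-3p (2.99) and miR-376b-5p (1.75) were called here too. miR-7a-5p (1.23), miR-3068-5p (1.08), miR-24-3p (0.78), miR-411-3p (1.13) and miR-379-5p (0.49) were not. In the fit without DIV5 control libraries 1 and 5, 319 were called, 278 of them also called with all libraries, and miR-7a-5p, miR-24-3p, miR-411-3p and miR-379-5p were then among them at similar values (1.28, 0.83, 1.17 and 0.53). With all libraries no single miRNA had a called difference between the changes with and without GDNF. Camera with all libraries did not call the other lists: let-7 8 up and 5 down (adjusted p = 0.298), miR-9 and neurogenic 2 and 6 (0.298), miR-290 and miR-302 0 and 2 (0.262), dopaminergic 1 and 0 (0.462), oligodendrocyte 1 and 2 (0.298), astrocyte 4 and 1 (0.298), erythroid 1 and 2 (0.82), vascular 1 and 4 (0.298), epithelial 1 and 2 (0.961) and stress 4 and 1 (0.262). For the epithelial list camera's direction was up and the median -0.44. In fry the neuron-enriched (adjusted p = 7.29e-05), stress (9.38e-06), astrocyte (0.0015) and dopaminergic (0.0031) lists passed upward. The oligodendrocyte (2.99e-05), miR-290 and miR-302 (0.00176), miR-9 and neurogenic (0.0031) and vascular (0.0316) lists passed downward. The let-7, erythroid and epithelial lists did not pass. Camera without a filter called the neuron-enriched (0.000538), let-7 (0.00124) and stress (0.00397) lists higher. Within the DIV5 batches 191 (replicates 1 and 2) and 306 (replicates 3 to 5) were called, and all 4 lists called with all libraries were called in each batch as well.

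**Figure D3:**
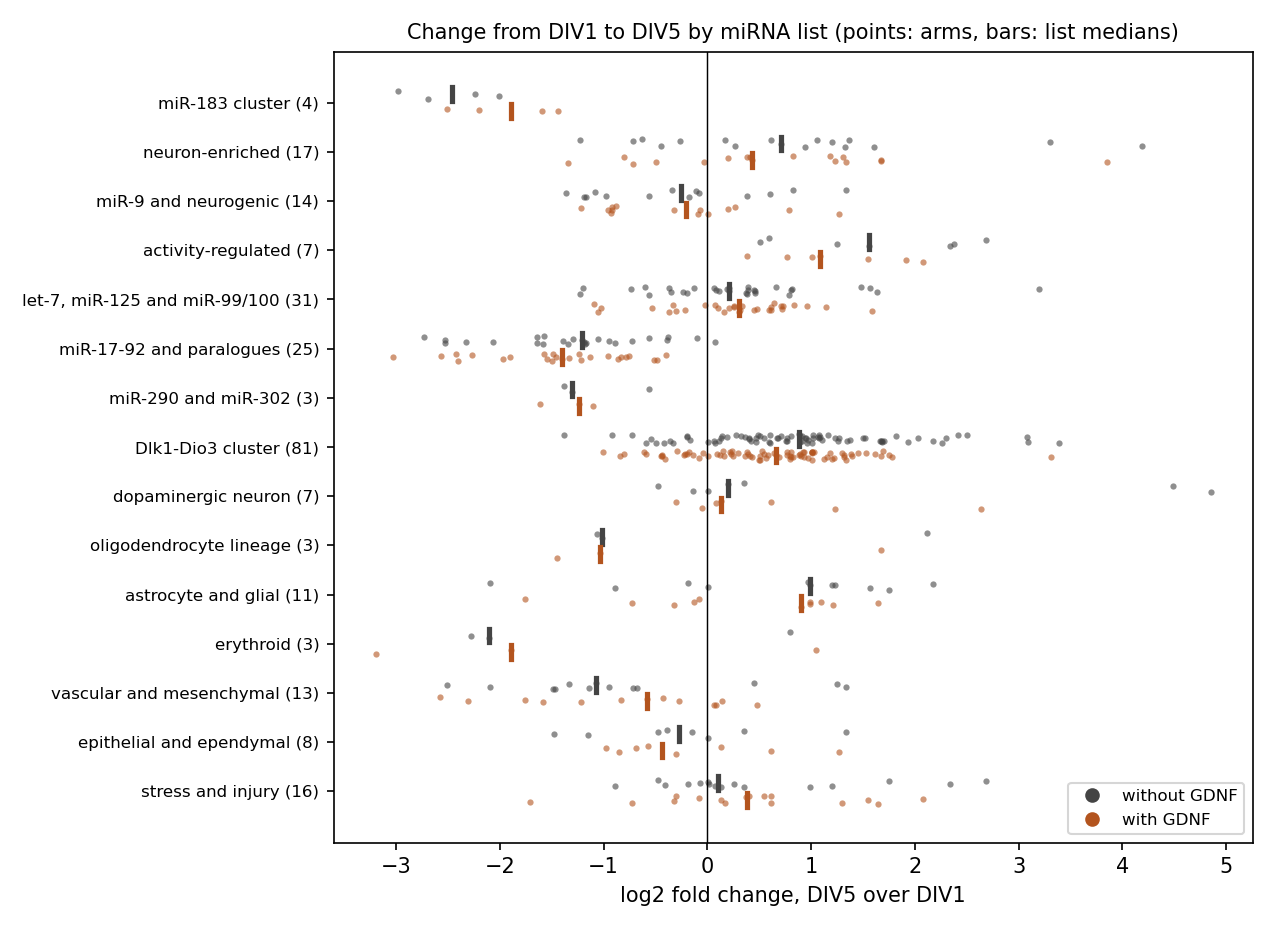
Log2 fold change of DIV5 over DIV1 (horizontal axis) for the arms of the 15 tested lists, without and with GDNF. Points are arms, thick bars are list medians and numbers beside the names are arms tested; the miR-17-92 medians lie at -1.20 and -1.40, the Dlk1-Dio3 medians at 0.89 and 0.66 and the activity-regulated medians at 1.56 and 1.09.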

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

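Of the tests reported here, those on the arms raised in DIV5 control libraries 1 and 5, the ones on miR-182-5p in which these libraries or a batch were set apart, the splits that part pairs and the sorting of splits by batch were chosen only after the result was seen. A test of the difference between the GDNF effects at the 2 days brought up 1 result: the miR-183 cluster list rose more with GDNF at DIV5 than at DIV1 (camera adjusted p = 0.0158), a call that was absent with an estimated correlation (adjusted p = 0.895; over 32 alternatives adjusted p between 7.62e-11 and 0.944). In addition, 38 of 284 group values had a library far from the other 4 of its group, by the gap to the nearest library over the whole range. Of these, 16 belong to 5 arms chosen after their values were seen. Without those arms it was 22 of 264, where chance gives about 1 in 20.

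Several of these share a replicate number. In replicate 1, miR-199a-5p was highest at DIV1 without GDNF (185.3 CPM against at most 19.63 CPM, gap over range 0.987), at DIV1 with GDNF (180.6 CPM, 0.904) and at DIV5 with GDNF (182.1 CPM, 0.893), and lowest in the DIV5 control (12.72 CPM, 0.75). The joined arm miR-199b-3p/199a-3p was highest in the same 3 libraries (0.958, 0.966 and 0.948), as was miR-214-3p (0.807, 0.921 and 0.819). These arms are known from mesenchymal cells, and they were chosen after their values were seen. miR-10a-5p and miR-10b-5p, encoded among Hox genes and known from posterior tissue, were highest in replicate 5 at DIV1 without GDNF (278.8 CPM, 0.906, and 339.2 CPM, 0.946) and with GDNF (343.2 CPM, 0.955, and 423.8 CPM, 0.952), and in replicate 2 at DIV5 with GDNF (139.6 CPM, 0.923, and 240 CPM, 0.793). At DIV5 they were also high in control libraries 1 (77.29 and 138.1 CPM) and 2 (148.1 and 177.7 CPM), against at most 1.78 and 7.57 CPM in control libraries 3 to 5. miR-143-3p was higher in replicates 1 and 2 than in 3 to 5 as well, with 1306 and 1087 CPM against at most 530.9 CPM in the DIV5 controls and 1756 and 1378 CPM against at most 579.5 CPM with GDNF. Whether the division of replicates 1 and 2 from 3 to 5 is one of sequencing, dissection or tissue was not tested. The leukocyte miRNA miR-142a-5p was highest in replicate 2 at DIV5 without (0.725) and with GDNF (0.762).

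The other libraries far from their group were these, with the gap over the range. At DIV1 without GDNF, replicate 1 was highest in miR-6516-5p (0.747), miR-673-5p (0.766) and miR-434-3p (0.782), replicate 2 lowest in miR-7a-5p (0.72), replicate 4 highest in miR-19a-5p (0.713) and replicate 5 highest in miR-132-3p (0.718). At DIV1 with GDNF, replicate 1 was highest in miR-127-3p (0.758) and miR-185-5p (0.748), replicate 3 in miR-455-3p (0.75) and replicate 5 in miR-204-5p (0.722), and replicate 5 was lowest in miR-302d-3p (0 reads, 0.836). At DIV5 without GDNF, replicate 2 was highest in miR-26a-5p (0.796) and had the lowest TMM factor (0.735), and replicate 5 was highest in miR-455-3p (0.734). At DIV5 with GDNF, replicate 1 was highest in miR-3473d (0.713) and miR-219a-2-3p (0.779) and lowest in miR-486a/b-5p (0.765), replicate 2 was highest in miR-128-3p (0.898), replicate 4 in miR-673-5p (0.741) and replicate 5 in miR-219a-1-3p (0.726).

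The first pattern weighed is the rise of miR-199 and miR-214 in replicate 1. More vascular or mesenchymal cells in that culture would raise the other members of that list too. In the DIV1 libraries of replicate 1 the 3 arms lay a median of 3.18 log2 units above the other 8 DIV1 libraries, while the other 10 members lay 0.154 above (95% interval -0.463 to 0.571), which argues against a general gain of such cells. These 10 include miR-10a-5p (-1.29) and miR-10b-5p (-0.886), whose high levels in replicate 5 lower their values and the median. The highest of the 10, miR-152-5p (0.989), still lay below the lowest of the 3 arms (2.53). A gain of a single cell type rich in these arms stays open, as do differences between the embryos or dissections.

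The next pattern is the 40 of 439 arms, all with a mean of at least 10 CPM, that were at least 2-fold higher in DIV5 control libraries 1 and 5 than in the other DIV5 controls (median 3.79-fold, up to 21.4-fold for miR-3068-5p), with 0 arms lowered as much. More transcription of their genes as the general cause is argued against by the 30 tested other arms of the same hairpins, whose median log2 excess was 0.0419 (95% interval -0.187 to 0.424) against 1.89 for the raised arms. Some of these other arms were higher too: miR-344f-5p 2.49-fold, miR-382-3p 2.1-fold, miR-379-3p 2.03-fold, miR-30b-5p 2.02-fold and miR-667-5p 2.01-fold. For those hairpins more transcription stays open. A swap with another of the 20 libraries is argued against as well, since the highest median excess elsewhere was 0.16. A library or sequencing step that acts on single arms stays possible. Across 101 hairpins the shifts of the 5p and 3p arms had r = 0.0506 (-0.104 to 0.241), whereas their changes between the days had r = 0.693 (0.541 to 0.798). Most of these hairpins hold no raised arm, where a low r can come from noise, and no other pair of libraries was compared. Arm-specific turnover could also give a low r, so this comparison cannot decide between them. The labels name no such step, these libraries lie in different depth batches, and arm-specific turnover of miRNAs in those cultures was not tested.

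The last pattern is the higher level of miR-182-5p with GDNF at DIV5. Without the 2 control libraries that stand apart its log2 value was 1.36 (SE 0.301) in place of 1.46 (SE 0.277); the call ended (adjusted p = 0.053) with 3 controls left. The lower of its values within the 2 DIV5 batches was 1.06 (SE 0.184, to which the spread of the DIV1 libraries contributes). If GDNF had slowed the change from DIV1 to DIV5 in general, other miRNAs that fell at least 4-fold would lie higher with GDNF. The mean of their medians over 10 splits of the controls (5 to 18 miRNAs) was -0.168. The 95% bootstrap bounds over miRNAs, averaged over the splits, were -0.392 and 0.0972. The splits overlap and miRNAs are not independent, so these bounds are descriptive. These values argue against each explanation as the whole cause, and an effect of GDNF on this cluster in the cultured cells remains a hypothesis that may account for it, found and tested on the same libraries.

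Other groupings of the same libraries were compared with the real ones, 100 for each result. For DIV5 against DIV1 chance can be excluded: 1 grouping, the real one, gave as many calls without GDNF (329, highest other 209) and with GDNF (284, highest other 149). Regrouping cannot tell the day from a library or sequencing batch that follows it. Reads without a feature were 20.68% at DIV1 and 14.81% at DIV5 without GDNF (exact permutation p = 0.0159, adjusted p = 0.0636). With GDNF they were 18.9% and 14.13% (exact permutation p = 0.0952, adjusted p = 0.19). At DIV5 this share was 17.69% to 19.51% in replicates 1 and 2, within the DIV1 range of 16.53% to 22.57%. In replicates 3 to 5 it was 9.506% to 13.31%. The fits with DIV5 replicates 1 and 2 only, given above, still called miRNAs between the days. These values argue against a batch marked by this share as the whole cause of the day calls. Another batch that follows the day stays open. For GDNF at DIV5 chance cannot be excluded: 20 of 100 groupings gave at least the 1 call, up to 110, and 5 of 100 gave a p of the miR-183 list as small as the real 8.96e-08 (smallest other 7.81e-15). The many calls point to a structure of the samples. Of 12 groupings with over 10 calls, 11 put at least 3 of the 4 libraries of DIV5 replicates 1 and 2 in 1 group (52 of all 99 others did) and 9 put DIV5 control libraries 1 and 5 together (45 of 99 did); the remaining 3 held all 4 batch libraries in 1 group. The real grouping has 2 of the 4 in each group, and of the 47 others that share this, 3 gave at least 1 call, up to 16. Within the batches the log2 value of miR-182-5p was 1.06 and 1.91. For the count of GDNF at DIV1 (0 calls in edgeR, 7 at an unadjusted p under 0.05, 0 in DESeq2 and limma voom) and of the difference (0 calls, highest other 3; 50 at an unadjusted p under 0.05, 0 in DESeq2 and limma voom) every grouping must give as many (100 of 100), so the comparison says nothing about chance. For the p of the miR-183 list at DIV1, 2 of 100 groupings gave one as small (real 0.00137, smallest other 0.000282), a share under 0.05. This is no independent evidence, since the series title names members of the list, and the list was not called with an estimated correlation (adjusted p = 0.908), in fry (0.948) or without DIV1 control library 1 (0.0674) or 5 (0.0562) or DIV1 GDNF library 5 (0.228). Among the 16 groupings that part all 5 same-number pairs at DIV5, 2 gave as many calls (real 1, highest other 1), and with the replicate term within day 1 did (real 3, highest other 1); 16 are too few for a share under 0.05.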

How the results depend on the processing

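The replicate term within each day, the fits without DIV5 control libraries 1 and 5, the fits within a DIV5 batch and the exact test of single miRNAs were chosen after seeing the data. Between the days, the counts of called miRNAs stayed within 1.5 times the reported ones under every alternative run, from 303 to 344 without GDNF and from 257 to 287 with GDNF when 1 library was left out. Of the called values, 1 changed sign: the median of the miR-183 list for the difference of the GDNF effects was -0.04 in place of 0.67 in DIV5 replicates 1 and 2, where it was not called (adjusted p = 0.944; over 32 alternatives from 7.62e-11 to 0.944). Differences in total count and in miRNAs detected with GDNF, none of them called, did so when 1 library was left out.

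The count for GDNF at DIV5, 1 in edgeR, was 2 with upper-quartile scaling, 13 with a filter at 10 CPM (444 miRNAs tested), 0 in a fit of only the groups compared, 26 in DESeq2, 3 with the replicate term within day, 0 without the 2 libraries that stand apart, 4 with both of these, and 2 in each DIV5 batch. Leaving out 1 library gave 0 (without DIV5 GDNF library 1 or 2) to 43 (without DIV5 control library 2; 32 without 3 and 37 without 4). At DIV1 the count was 2, miR-6239 and miR-1957a, without the 2 libraries and with the replicate term, and the count for the difference was then 5, with miR-182-5p among them; it was 1, miR-182-5p, in DIV5 replicates 3 to 5, and 0 to 1 (without DIV5 control library 2) with 1 library left out.

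miR-182-5p at DIV5 lost its call in the fit of only the groups compared (log2 1.46, adjusted p = 0.442) and without the 2 libraries (1.36, adjusted p = 0.053); leaving out 1 library gave 1.30 to 1.84, and the adjusted p ranged from 8.41e-07 to 0.442. miR-183-5p at DIV5 passed in DESeq2 (1.03, adjusted p = 0.0257), with the replicate term within day (1.24), with that and without the 2 libraries (1.39), in replicates 3 to 5 (1.76) and in the exact permutation test (1.03, adjusted p = 0.0346), and leaving out 1 library gave 0.85 to 1.43 (adjusted p over all from 9.07e-05 to 0.469). At DIV1 the exact permutation test alone passed miR-182-5p (0.36) and miR-183-5p (0.48). Apart from fewer libraries or miRNAs tested, the cause was not tested.

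The correlation of the GDNF effects at the 2 days was -0.123 with miRNAs of at least 10 CPM and -0.115 to -0.0058 with 1 library left out. With 1 library left out, the difference in total count was 1466900 to 2282600 between days without GDNF, -153430 to 181800 for GDNF at DIV1 and -307400 to 508330 at DIV5; in miRNAs detected it was 140.8 to 213.3, -47.7 to 20.55 and -33.7 to 38.8; and in the share of the 5 most abundant for GDNF at DIV5 it was 1.75 to 3.47 percentage points (exact p = 0.0397 without DIV5 control library 2). Upper-quartile scaling moved the median of the difference of the GDNF effects by 0.116 (log2). Depth limits the rarer miRNAs: 1 read is worth 0.231 to 0.942 CPM in the DIV5 controls, where miR-96-5p had a mean of 1.77 CPM, and up to 2.38 CPM at DIV1.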
